A study of Danio rerio with 12 samples.

How the data were processed

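Polyadenylated RNA of zebrafish ovary was sequenced in 12 libraries, with 3 libraries for each of 4 groups: wild type and adamts9 mutant at 47 days post fertilization (dpf), and wild type and mutant at 61 dpf. Genotype, age and replicate number were taken from the sample labels. The series' design text gives other ages than the sample labels do, and the ages of the labels are used throughout. The labels do not say whether the replicates are separate animals or pools, so p-values measure the spread between these samples, which may be technical in part.

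The authors deposited 1 table of estimated counts per gene symbol, with 1 column per library. Per the submitters' processing notes, kallisto and the GRCz11 assembly were used. Their versions, the annotation release and the way transcripts were summed to genes are not given in the sources used here. The deposited table held 26172 lines, of which 45.4% of the values were not whole (tolerance 1e-06), as estimated counts need not be. The line without a gene name, at most 0.000113% of a library, was left out of library sizes and tests. Of the 26171 named genes, 17 carried a spreadsheet date in place of a symbol, 275 were at 0 in every library, and 47 with over 120 counts in all had the same 12 values as another gene to 3 decimals. Counts of near-identical copies, such as the vitellogenin and globin genes, may be divided between copies by the estimation and are uncertain for a single copy.

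Total counts ranged from 16456573 (mutant at 47 dpf, replicate 2) to 38754785 (wild type at 61 dpf, replicate 1). A count of 0 allows up to 3 counts, which is 0.0774 to 0.182 CPM across the libraries. This floor covers counting error only, and the reads carry no molecular identifiers in the sources used here. The binomial interval given for a share of called genes takes genes as independent, which neighbours on a chromosome need not be.

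The estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr on the 4 groups, which left 21407 genes. Library sizes were scaled by TMM, and all 12 libraries were fitted in 1 edgeR quasi-likelihood model with a 4-level group factor (common biological coefficient of variation 0.33). The contrasts were mutant against wild type at each age, the difference between those 2 contrasts, and 61 against 47 dpf in each genotype. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested). Every adjusted p of a gene is from this edgeR test, log2 fold changes are given with their standard error (SE), and CPM values are scaled by TMM. For adamts9 and for measures of library composition, exact two-sided permutation tests of 3 against 3 libraries were used, which cannot give a p below 0.1.

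Before the data were examined, 25 gene lists with 700 members were written down from general knowledge of fish gonads, of which 658 members had a line in the table: oocyte, meiosis, germ cell and piRNA, granulosa cell, steroidogenesis, testis somatic cell, spermatid and axoneme, collagen and basement membrane, proteoglycan and matrix glycoprotein, ADAMTS family, MMP and TIMP, steroid and progestin receptor, Wnt target and regulator, cell cycle, apoptosis and p53, macrophage and neutrophil, lymphocyte, erythroid, endothelial and mural, vitellogenin, liver, exocrine pancreas, skeletal muscle, adipocyte, and immediate early. The lists of other tissues and blood cells are there because an ovary dissection could hold those cells. Each list was tested against all other genes with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data, and the rotation test fry, were run as alternatives.

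Genes named in the text followed a rule fixed before the data were examined. It took 20 key genes of gonad biology, of which 18 were tested (nobox has no line in the table and nanos2 did not pass the filter). For each mutant comparison it took the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the CPM of the groups and a symbol that is not a clone or locus name, and for the age comparisons 4 of each. It took the 3 members with the smallest p of each list called in a mutant comparison, up to 2 members of a list that was not called, and the 6 genes with the smallest p for the difference between ages. Genes with a date for a name were also passed over, as they carry no symbol.

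The position of genes relative to adamts9 came from a RefSeq gene table of another assembly, GRCz12tu. For that reason it was used only for the order of genes and for which genes share a chromosome, and no coordinates are given. It placed 19882 of the named genes. Of the named genes, 17807 have a symbol in the table of gene IDs used here.

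Alternatives fixed before the data were examined were other scaling (the median-of-ratios factors, and the upper quartile), no filter on low counts, DESeq2's Wald test, limma voom, a fit of the compared libraries alone, the replicate number as a block, removal of the 50 most abundant genes, a minimum fold of 2, and leaving out each library in turn. Counts without the chromosome of adamts9 and on each other chromosome, the medians of lists without a library, and the alternatives for the lists and genes of the age comparisons, for the difference of the mutant effect and for the overlap of the ages, were chosen after seeing the data. No pair of libraries of the same group was alike within sampling noise.

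In simulated counts 200 genes were changed by a fold of 2, 4 or 8, and a further list of genes was shifted up by a fold of 2. Of the 200, the edgeR test recovered 11.9% at a fold of 2, 59.7% at 4 and 84.8% at 8 for the comparison at 47 dpf (21057 genes, 9 false among 117 calls). Calls of genes in the shifted list are part of all calls and were not counted as false. For the comparison at 61 dpf the shares were 11.9%, 61.2% and 89.4% (21064 genes, 2 false among 110 calls). In both, camera called the shifted list and 0 of the 24 lists without a shift. The simulated genes were drawn independently of each other, each with the same spread in all groups. The simulation therefore cannot test the preset correlation for lists whose members vary together, such as exocrine pancreas (estimated correlation 0.97) and liver (0.582). The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.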

Results

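Ovaries of wild-type zebrafish and of adamts9 mutants were compared at 47 and 61 dpf. adamts9 encodes a secreted metalloprotease of the extracellular matrix. Each of the 4 groups had 3 libraries. Total counts were 23723503 to 27678543 in wild type and 16456573 to 29277646 in mutant at 47 dpf, and 21702444 to 38754785 in wild type and 17612727 to 26031412 in mutant at 61 dpf.

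The adamts9 transcript was at 16.7 ± 2.67 CPM in wild type and 14.3 ± 1.07 CPM in mutant at 47 dpf (mean ± SD, n = 3 each; exact permutation p = 0.3). At 61 dpf it was at 13.8 ± 3.35 CPM in wild type and 14.5 ± 1.59 CPM in mutant (exact permutation p = 0.8, n = 3 each). The log2 fold changes were -0.22 ± 0.22 (SE, edgeR adjusted p = 0.969) and 0.06 ± 0.22 (adjusted p = 0.886). Without wild-type replicate 1 the value at 61 dpf was -0.11. The level of this transcript therefore does not check the genotype labels.

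The 4 groups also differed in how closely their libraries resembled each other. The median SD of log2 CPM per gene was 0.443 in wild type at 61 dpf and 0.229 to 0.302 in the other groups. Ribosomal protein genes took 1.43% ± 0.191 of the counts in wild type and 1.88% ± 0.0878 in mutant at 61 dpf (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Mitochondrial genes took 1.56% ± 0.587 and 0.907% ± 0.156 (exact permutation p = 0.2, n = 3 each). The first principal component of log2 CPM held 26.2% of the variance. The wild-type libraries of 61 dpf lay at 42.8 to 105.55 on it, above the other 9 libraries, which lay between -59.05 and 1.12.

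In mutant ovary at 47 dpf, ogfrl2 rose from 2.05 ± 0.384 to 42.6 ± 14.4 CPM (SD, n = 3 each), a log2 fold change of 4.38 ± 0.34 (SE, edgeR adjusted p = 0.000181). fn1b, a fibronectin of the extracellular matrix, rose by 2.86 ± 0.42 (adjusted p = 0.0268). The planar polarity gene prickle2b rose by 2.06, the keratin gene krt18a.1 by 1.49, and c6, a component of complement, by 1.42. rpusd4, a pseudouridine synthase gene, fell from 48.7 ± 4.04 to 7.99 ± 0.823 CPM (log2 fold change -2.61 ± 0.18, adjusted p = 0.000129). The opsin gene opn6a (-3.21), tmf1 (-2.38), cdk5rap1 (-1.90), uba3 (-1.82), which encodes a subunit of the NEDD8-activating enzyme, and phf2 (-1.32), a histone demethylase gene, also fell. Of the genes named here, ogfrl2, prickle2b and all that fell were placed on the chromosome of adamts9, as described below.

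In all, 19 of 21407 genes were called at 47 dpf, 10 higher and 9 lower in mutant, and 1481 had an unadjusted p under 0.05. Among the key genes of the gonad none was called by edgeR at this age. cyp19a1a, the aromatase gene, had a log2 fold change of 1.47 (adjusted p = 0.745), the progestin receptor gene pgr 0.96 (adjusted p = 0.41) and gdf9, an oocyte growth factor gene, -0.40 (adjusted p = 0.557). Of the 11 named genes, 6, 5 and 6 were called without mutant replicates 1, 2 and 3, and 8, 4 and 5 without wild-type replicates 1, 2 and 3. DESeq2 called 173 genes and a test against a fold of 2 called 10.

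Several groups of extracellular matrix and somatic genes were higher as groups in mutant at 47 dpf, by camera with the preset correlation. Ovary RNA cannot tell higher expression per cell from a larger share of the cells that express a list. This holds for all lists below. The collagen and basement membrane list (median log2 fold change 0.32, 35 of 44 members positive) had an adjusted p = 7.39e-07, and an adjusted p = 0.151 with an estimated correlation. No member of the list was called over all genes, and 12 were higher and 1 lower adjusted over the list alone. Among them col5a2a had a log2 fold change of 1.2 (adjusted p = 0.115 over all genes) and col1a2 of 1.83 (adjusted p = 0.183). In the proteoglycan and matrix glycoprotein list (median 0.19, adjusted p = 0.00608, 0.156 with an estimated correlation) fn1b was the 1 member called over all genes, and 4 were higher adjusted over the list alone. The MMP and TIMP list, matrix proteases and their inhibitors, had a median of 0.19 (adjusted p = 0.00467, and adjusted p = 0.156 with an estimated correlation), with mmp11b at 3.72 (adjusted p = 0.166), none called over all genes and 1 higher adjusted over the list alone. The ADAMTS family had a median of 0.26, and 14 of 17 members were positive (adjusted p = 0.0205, and adjusted p = 0.485 with an estimated correlation). No member was called over all genes or adjusted over the list alone. The call of the ADAMTS family ended without mutant replicate 2 (adjusted p = 0.0926), wild-type replicate 2 (0.0769) and wild-type replicate 3 (0.078), without which its median was 0.16. The proteoglycan median was 0.10 without mutant replicate 2 or wild-type replicate 2 and 0.065 without mutant replicate 3, and the MMP and TIMP median was 0.10 without mutant replicate 2 and 0.11 without wild-type replicate 3.

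The testis somatic cell list had a median of 0.34 at 47 dpf (14 of 18 positive, adjusted p = 0.00123, and adjusted p = 0.151 with an estimated correlation). Its members aldh1a2, which encodes a retinoic acid synthesis enzyme, and wt1a, a gonad transcription factor gene, had log2 fold changes of 1.43 (adjusted p = 0.0989) and 1.5 (adjusted p = 0.169). None was called over all genes and 3 were higher adjusted over the list alone. The granulosa cell list had a median of 0.35 (21 of 26 positive, adjusted p = 0.00608, and adjusted p = 0.151 with an estimated correlation), with 0 members called over all genes and 1 adjusted over the list alone. Without wild-type replicate 2 its adjusted p was 0.0535. The endothelial and mural list had 28 of 28 members positive (median 0.38, adjusted p = 3.16e-06, and adjusted p = 0.151 with an estimated correlation) and no member called either way. The immediate early list, which holds stress and growth response genes such as egr1 (1.55, adjusted p = 0.166), had a median of 0.23 (adjusted p = 0.00535, and adjusted p = 0.18 with an estimated correlation). None of its members was called over all genes, 4 were higher adjusted over the list alone, and its adjusted p was 0.123 without mutant replicate 1. Its median was then 0.085, and 0.34 and 0.42 without mutant replicate 3 and wild-type replicate 1. The testis somatic cell median was 0.19 without mutant replicate 3.

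Markers of other cells and tissues were also higher as groups in mutant at 47 dpf. The macrophage and neutrophil list had a median log2 fold change of 1.42 at 47 dpf, with 26 of 28 members positive (adjusted p = 2.02e-12, and adjusted p = 0.156 with an estimated correlation). No member was called over all genes and 19 were higher adjusted over the list alone, such as cd74a (1.94, adjusted p = 0.0672 over all genes). The mean log2 CPM of the list was 3.18, 1.6 and 2.07 in mutant replicates 1, 2 and 3 and 1.08 to 1.46 in wild type, and without mutant replicate 1 the median log2 fold change was 0.70, which did not end the call. The liver list had a median of 1.82, with 23 of 23 members positive (adjusted p = 4.44e-09, and adjusted p = 0.275 with an estimated correlation), 0 called over all genes and 7 higher adjusted over the list alone. Its summed level was 401 CPM in mutant replicate 1, 63.2 and 88 CPM in the other mutant libraries and 41.3 to 76.2 CPM in wild type, and its median was 0.49 without mutant replicate 1. The exocrine pancreas list had a median of 2.19 (adjusted p = 0.00321, and adjusted p = 0.623 with an estimated correlation), and its summed level was 1170, 30.3 and 2490 CPM in mutant replicates 1, 2 and 3 and 8.11 to 640 CPM in wild type. That call ended without mutant replicate 1 (adjusted p = 0.123), mutant replicate 3 (0.24) or wild-type replicate 2 (0.624), and the median was 1.18 without mutant replicate 3 and 3.87 without wild-type replicate 1. The skeletal muscle list had a median of 2.33 (adjusted p = 0.00467, and adjusted p = 0.621 with an estimated correlation), with 664 CPM in mutant replicate 2 and 22.1 to 92.5 CPM in the other libraries of this age. Its direction turned without mutant replicate 2 (median -0.23, adjusted p = 0.926), and the call ended without wild-type replicate 1 (0.171) or replicate 2 (0.0993). No pancreas or muscle gene was called over all genes or adjusted over the list alone.

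**Figure D1:**
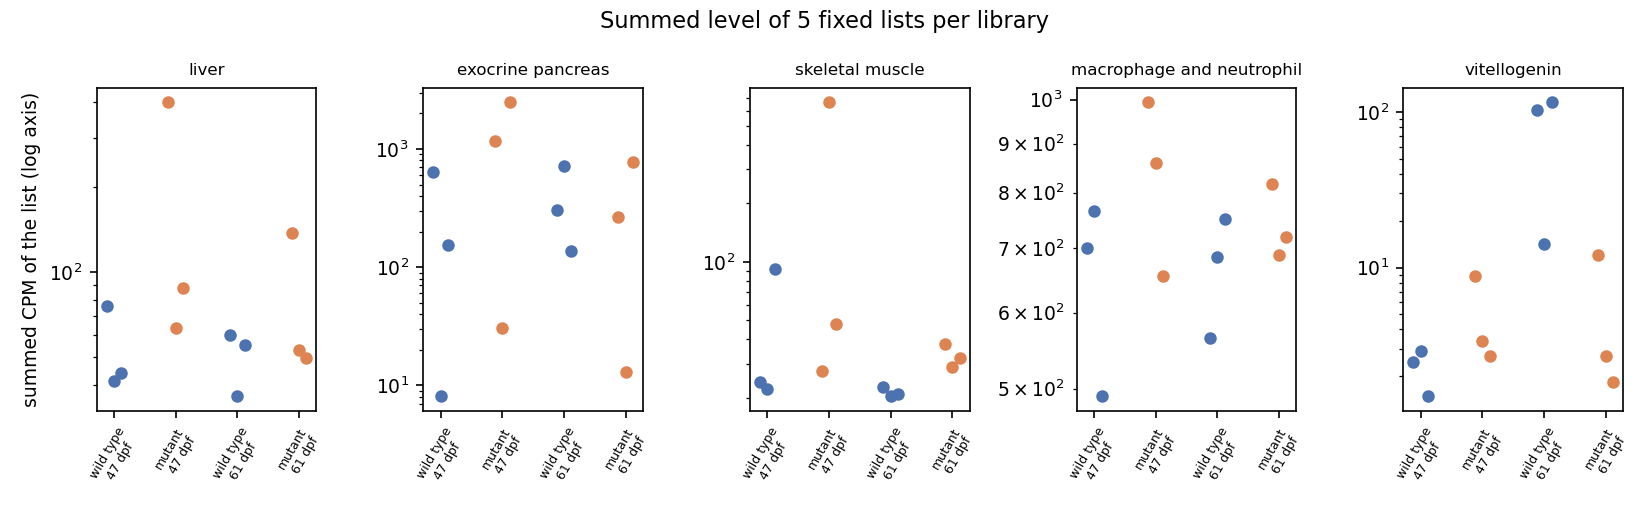
Summed CPM of 5 fixed lists in each library (log axis), with 3 dots per group. Single libraries stand apart at 47 dpf, with liver at 401 CPM in mutant replicate 1 and muscle at 664 CPM in mutant replicate 2, and vitellogenin reached 103, 14.1 and 116 CPM in the wild-type libraries of 61 dpf.

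The remaining lists were not called at 47 dpf. Camera's adjusted p was 0.507 for oocyte, 0.182 for meiosis, 0.814 for germ cell and piRNA, 0.86 for steroidogenesis, 0.86 for spermatid and axoneme, 0.968 for steroid and progestin receptor, 0.426 for Wnt target and regulator, 0.752 for cell cycle, 0.728 for apoptosis and p53, 0.0742 for lymphocyte, 0.968 for erythroid, 0.426 for vitellogenin and 0.226 for adipocyte. The median and mean were above 0 and camera's direction was down for the oocyte, germ cell and piRNA, and erythroid lists. They were below 0 with an upward direction for the steroid and progestin receptor list, and the mean alone differed in sign from camera for steroidogenesis, cell cycle and apoptosis, and the median alone for spermatid and axoneme. The lymphocyte list was called without mutant replicate 2 (adjusted p = 0.0298) or wild-type replicate 1 (0.0177), and the meiosis list without mutant replicate 3 (0.029).

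In mutant ovary at 61 dpf gsdf, a growth factor gene of somatic gonad cells, was at 44.8 ± 8.71 CPM against 15.3 ± 4.74 CPM in wild type (SD, n = 3 each). The log2 fold change was 1.55 ± 0.34 (SE, edgeR adjusted p = 0.0439). fshr, the receptor gene for follicle-stimulating hormone, was lower, at 4.28 ± 0.503 against 9.72 ± 2.18 CPM (log2 fold change -1.18 ± 0.24, adjusted p = 0.0379). From 47 to 61 dpf in wild type gsdf fell (log2 fold change -2.10) and fshr rose (1.17). Between the ages in mutant edgeR called 0 genes. The other rises and falls given here are of mutant against wild type at 61 dpf. ogfrl2 rose by 4.63 and prickle2b by 2.12, and smoc2, a matrix protein gene, by 2.57, kbtbd8 by 2.56, stat1b, an interferon signalling gene, by 2.29, cdh4, a cadherin gene, by 2.28, and the membrane metalloprotease gene mmp16b by 2.23. tmf1 (-2.96), rpusd4 (-2.69), cdk5rap1 (-2.16), the septin gene sept5a (-2.15), cmah (-2.13) and olah (-3.05), a fatty acid thioesterase gene, fell. Of these genes, ogfrl2, prickle2b, kbtbd8, cdh4, tmf1, rpusd4 and cdk5rap1 were placed on the chromosome of adamts9.

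Of 21407 genes, 390 were called at 61 dpf, 262 higher and 128 lower in mutant, and 5418 had an unadjusted p under 0.05. With upper-quartile scaling 989 were called, 878 higher and 111 lower, so that the share of higher calls was 88.8% in place of 67.2%, and the median log2 fold change of all genes was 0.20 in place of 0.01. Other key genes were not called: bmp15 (-0.96, adjusted p = 0.0812), figla (0.91, adjusted p = 0.065), cyp19a1a (-0.33, adjusted p = 0.798), amh (-0.29, adjusted p = 0.575), dmrt1 (-0.80, adjusted p = 0.563) and ddx4 (0.79, adjusted p = 0.315). The number of calls was 36, 27 and 29 without mutant replicates 1, 2 and 3, 1639 without wild-type replicate 2 and 58 without wild-type replicate 3, and of the 34 named genes called, 11, 9, 10, 34 and 14 remained in these fits, and 20 without wild-type replicate 1. DESeq2 called 2387 genes, a fit of the compared libraries alone 20 and a test against a fold of 2 called 9.

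**Figure D2:**
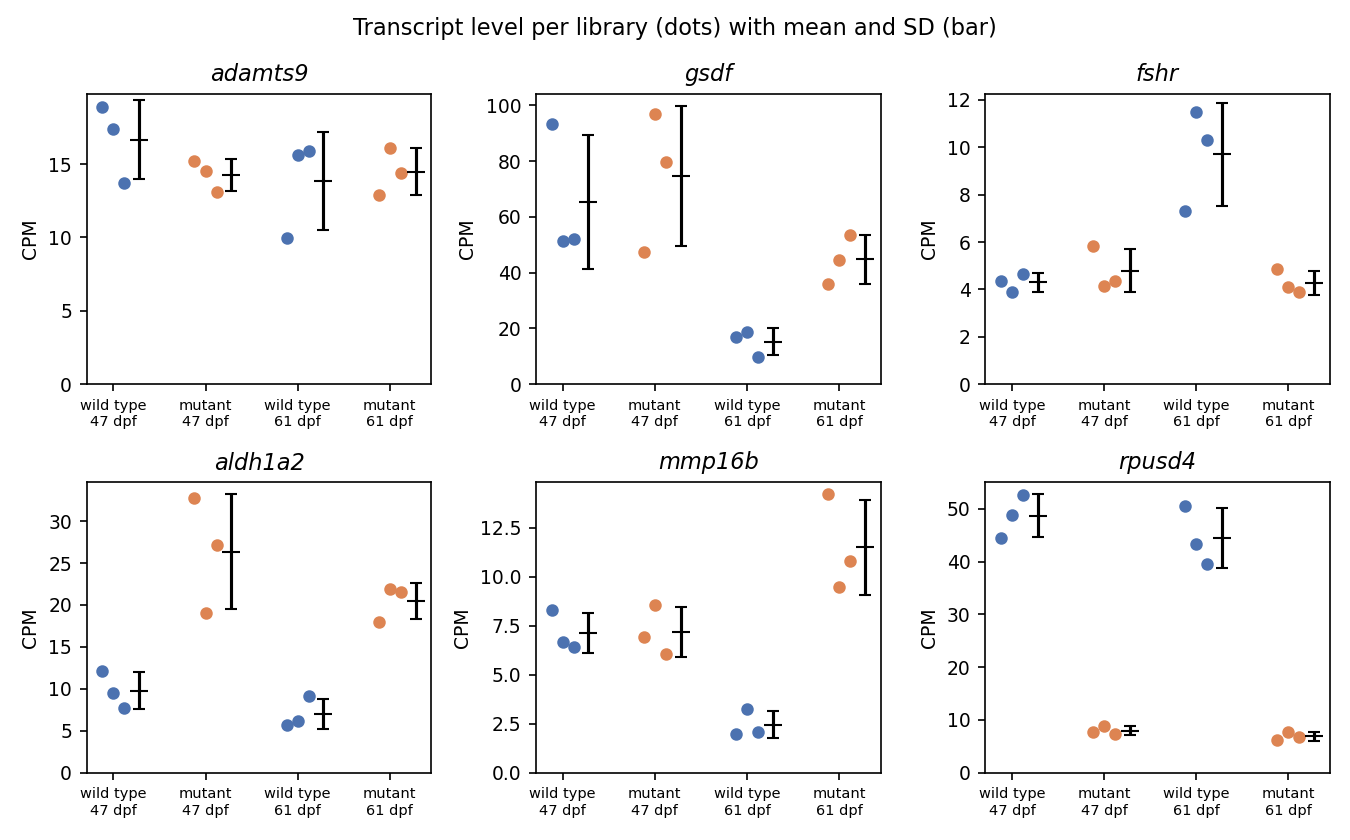
CPM of 6 genes per library (dots), with mean and SD beside them (3 libraries per group). adamts9 overlapped between genotypes at both ages, gsdf was at 15.3 CPM in wild type and 44.8 CPM in mutant at 61 dpf, fshr at 9.72 and 4.28 CPM, and rpusd4 was lower in mutant at both ages.

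Lists of matrix genes were higher as groups in mutant at 61 dpf, by camera with the preset correlation. The MMP and TIMP list had a median log2 fold change of 0.89 (25 of 29 positive, camera adjusted p = 2.55e-06, and adjusted p = 0.0558 with an estimated correlation). Of its members 4 rose over all genes, among them mmp16b, mmp14a (1.22, edgeR adjusted p = 0.0375) and mmp9 (1.31, adjusted p = 0.0391), and 11 adjusted over the list alone. The proteoglycan and matrix glycoprotein list had a median of 0.80 (32 of 38 positive, adjusted p = 3.78e-06, and adjusted p = 0.0558 with an estimated correlation). The fibrillin gene fbn2b (1.51) and the tenascin gene tnxba (1.04) rose over all genes, and 7 members adjusted over the list alone. The collagen and basement membrane list had a median of 0.64 (40 of 44 positive, adjusted p = 9.2e-07, and adjusted p = 0.162 with an estimated correlation). In it col4a5 (1.1) and col6a3 (0.90) rose over all genes, and 18 members were higher and 2 lower adjusted over the list alone. The ADAMTS family had a median of 0.30 (15 of 17 positive, adjusted p = 0.0324, and adjusted p = 0.746 with an estimated correlation) with no member called either way. Its call ended without mutant replicate 1 (adjusted p = 0.0613), wild-type replicate 1 (0.0598) or wild-type replicate 3 (0.31), and its median was 0.50 and 0.54 without wild-type replicates 1 and 2.

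The testis somatic cell list had a median of 0.50 at 61 dpf, with 12 of 18 members positive (camera adjusted p = 0.0117, and adjusted p = 0.252 with an estimated correlation). Of its members 5 were higher in mutant, over all genes and adjusted over the list alone. Among them were aldh1a2 (1.55, edgeR adjusted p = 0.0281), wt1b (1.99, adjusted p = 0.0306), and pdgfra, a growth factor receptor gene of mesenchymal cells (1.27, adjusted p = 0.0129). The list also holds gsdf, which was higher, and amh and dmrt1, which had negative log2 fold changes and were not called. Without wild-type replicate 1 the adjusted p of the list was 0.0598. In the macrophage and neutrophil list (median 0.56, adjusted p = 0.0324, and adjusted p = 0.839 with an estimated correlation) cd74a (1.57), cd74b (1.59) and coro1a (1.39) rose over all genes, and 4 members adjusted over the list alone. That call ended without mutant replicate 2 (adjusted p = 0.0727), wild-type replicate 1 (0.0562) or wild-type replicate 2 (0.384). The lymphocyte list had a median of 0.70 (adjusted p = 0.0344, and adjusted p = 0.37 with an estimated correlation), 0 members called over all genes and 1 adjusted over the list alone. It was not called without mutant replicate 1 (adjusted p = 0.053), wild-type replicate 1 (0.134) or wild-type replicate 2 (0.0696).

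The vitellogenin list, genes for yolk precursors that are made mainly by liver, had a median of -3.98 in mutant at 61 dpf, with 0 of 6 members positive (adjusted p = 1.9e-05, and adjusted p = 0.252 with an estimated correlation). vtg7 (-4.12, edgeR adjusted p = 0.0427) and vtg4 (-5.21, adjusted p = 0.0497) were lower over all genes, and 6 members adjusted over the list alone. The summed level was 103, 14.1 and 116 CPM in wild-type replicates 1, 2 and 3, and 12, 2.69 and 1.84 CPM in mutant replicates 1, 2 and 3. From 47 to 61 dpf the median change of the list was 6.25 in wild type and 0.19 in mutant (camera adjusted p = 0.916 in mutant). The liver list was not called at 61 dpf (median 0.82, adjusted p = 0.287). Its summed level was 60.1, 36.4 and 55.1 CPM in wild-type replicates 1, 2 and 3 of 61 dpf. In mutant replicates 1, 2 and 3 of that age it was 138, 53 and 49.5 CPM. Among these mutant libraries replicate 1 held the most of both lists.

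**Figure D3:**
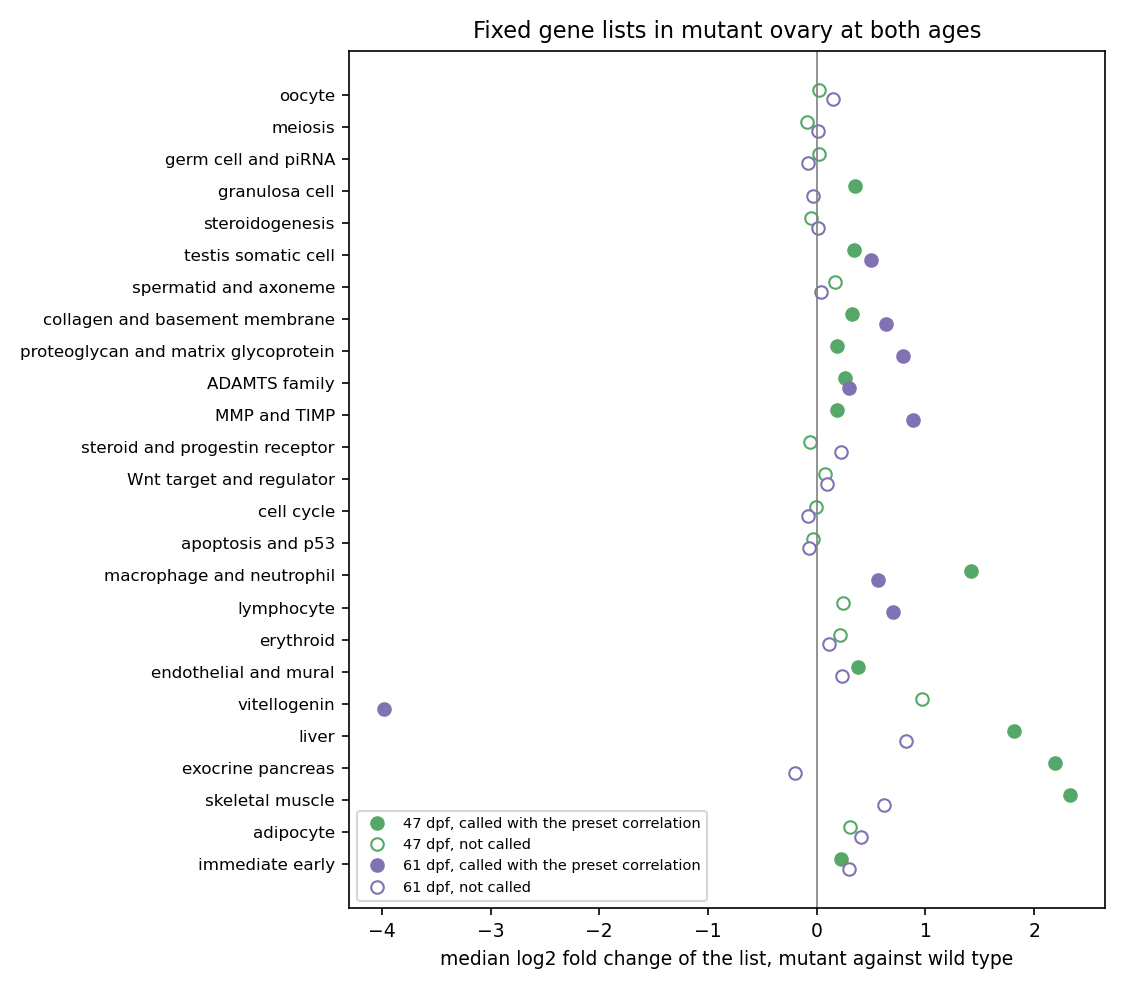
Median log2 fold change of each fixed list, mutant against wild type, at 47 dpf (green) and 61 dpf (purple), with filled dots for lists called with the preset correlation. MMP and TIMP genes had medians of 0.19 and 0.89, macrophage and neutrophil genes 1.42 and 0.56, and vitellogenin genes 0.97 and -3.98.

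The other lists were not called at 61 dpf. Camera's adjusted p was 0.218 for oocyte, 0.706 for meiosis, 0.706 for germ cell and piRNA, 0.868 for granulosa cell, 0.987 for steroidogenesis, 0.987 for spermatid and axoneme, 0.789 for steroid and progestin receptor, 0.521 for Wnt target and regulator, 0.61 for cell cycle, 0.706 for apoptosis and p53, 0.987 for erythroid, 0.237 for endothelial and mural, 0.218 for exocrine pancreas, 0.237 for skeletal muscle, 0.459 for adipocyte and 0.213 for immediate early. Single members of these lists that passed edgeR's test were nr3c1, the glucocorticoid receptor gene (-1.11, adjusted p = 0.0375), and cdkn1a, a cell cycle inhibitor gene (1.15, adjusted p = 0.0451), beside fshr of the granulosa cell list. The mean alone differed in sign from camera for granulosa cell and cell cycle, and the median alone for spermatid and axoneme and for erythroid. The oocyte list was called without wild-type replicate 1 (adjusted p = 0.00718), exocrine pancreas without mutant replicate 3 (0.00865) and immediate early without wild-type replicate 3 (0.0446). No list call in any comparison held with an estimated correlation.

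The mutant comparisons of the 2 ages share no libraries, but both came from 1 fit, which shares its estimate of each gene's spread. The expected numbers and Fisher's exact test take the calls of the 2 ages as independent, which such a fit need not give. Of the called genes, 6 were higher at both ages (0.122 expected of independent lists, Fisher's exact two-sided p = 6.4e-10) and 8 were lower at both (0.0538 expected, p = 1.17e-17). ogfrl2, prickle2b and krt18a.1 were among the first, and rpusd4, tmf1, uba3, cdk5rap1 and phf2 among the second. Counted after seeing the data, 2 of the 6 were placed on the chromosome of adamts9, 2 elsewhere and 2 not at all, and 7 of the 8 were placed on that chromosome and 1 not at all. Of the 19 genes called at 47 dpf, 18 had the same sign at 61 dpf, and of the 390 called at 61 dpf, 300 had the same sign at 47 dpf, against 63.4% of all tested genes. Along their direction at 61 dpf these 390 genes had a median log2 change of 0.24 at 47 dpf and 1.47 at 61 dpf, on which they were chosen. Genes higher at both ages were 3 without wild-type replicate 2 or 3 of 47 dpf, genes lower at both 5 without mutant replicate 1 of 61 dpf, and the 18 became 11 without wild-type replicate 2 of 47 dpf. The 300 became 170 and 60 without wild-type replicates 1 and 2 of 47 dpf, 149 and 121 without mutant replicates 2 and 3 of 47 dpf, 30, 20 and 23 without mutant replicates 1, 2 and 3 of 61 dpf, and 1297 and 48 without wild-type replicates 2 and 3 of 61 dpf.

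Genes called in mutant and placed in the gene order lay near adamts9 more often than other genes did. On the chromosome that holds adamts9 lay 10 of the 14 placed calls of 47 dpf (71.4%, 95% exact Clopper-Pearson interval 41.9 to 91.6), against 3.48% of the tested genes (Fisher's exact p = 2.15e-12). At 61 dpf it held 28 of 306 placed calls (9.15%, interval 6.17 to 13, Fisher's exact p = 3.34e-06). The other chromosome with the most calls held 1 at 47 dpf and 26 at 61 dpf (8.5% of placed calls against 5.73% of tested genes, Fisher's exact p = 0.0456, adjusted p = 0.228 over the 25 chromosomes). In gene order prickle2b lay 3 genes from adamts9, ogfrl2 15, cdh4 18, rpusd4 26, uba3 30, tmf1 31, kbtbd8 36, cdk5rap1 57, phf2 143 and opn6a 432. The median distance of called genes was 30.5 genes at 47 dpf and 40 genes at 61 dpf, and that of all tested genes there was 236 genes (permutation p = 1e-05 at both ages, one-sided, the smallest that 1e+05 permutations can give). Of the 19 calls at 47 dpf 4 were placed elsewhere, all higher, and 5 were not placed. Of the 390 at 61 dpf 278 were placed elsewhere (180 higher, 98 lower) and 84 were not placed. These counts were chosen after seeing the data. At 47 dpf 6 calls lay on the chromosome of adamts9 without mutant replicate 2 or wild-type replicate 2, and at 61 dpf 12, 10 and 10 without mutant replicates 1, 2 and 3, and 67 and 13 without wild-type replicates 2 and 3.

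**Figure D4:**
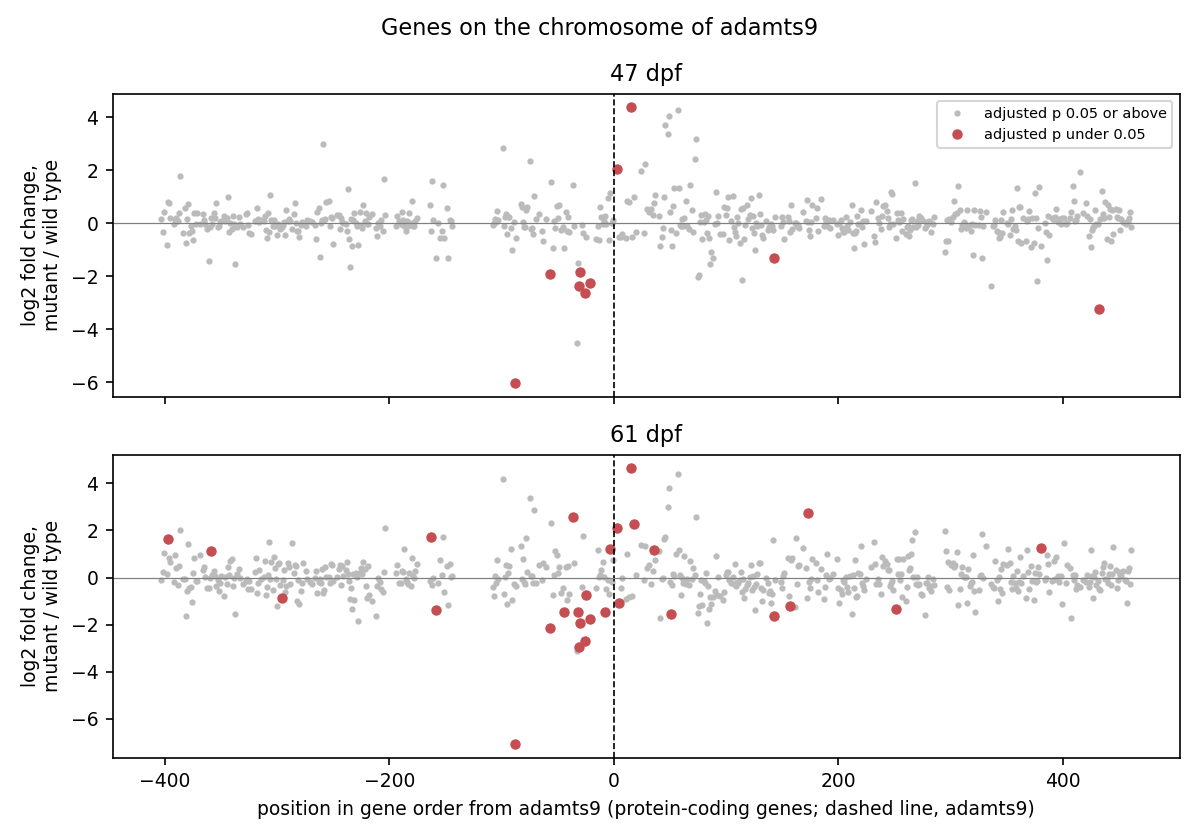
Log2 fold change, mutant against wild type, of the genes on the chromosome of adamts9 by their position in gene order, at 47 dpf (top) and 61 dpf (bottom), with called genes in red. The called genes gather around adamts9, at a median distance of 30.5 and 40 genes.

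From 47 to 61 dpf in wild-type ovary vtg1, a yolk precursor gene, rose from 0.322 ± 0.0523 to 44.6 ± 31.2 CPM (SD, n = 3 each), a log2 fold change of 7.09 ± 1.52 (SE, edgeR adjusted p = 0.0459). The apolipoprotein gene apoeb rose by 6.01, s100t by 3.51 and stm, an otolith matrix gene, by 3.26, and fshr rose by 1.17 (adjusted p = 0.0385). The globin genes hbaa1 (-3.53) and hbba1 (-3.27), cntnap3 (-3.06) and ptk2bb (-4.43) fell, and so did gsdf (-2.10 ± 0.34, adjusted p = 0.0239). In all 325 genes were called, 156 higher and 169 lower at 61 dpf, and 4627 had an unadjusted p under 0.05. With upper-quartile scaling 92 were higher and 220 lower, so that 29.5% of the calls were higher in place of 48%.

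By camera, the vitellogenin list (median 6.25, adjusted p = 6.51e-06, and adjusted p = 0.357 with an estimated correlation) rose with age in wild type, with 4 of 6 members called over all genes and 6 adjusted over the list alone. The macrophage and neutrophil list rose too (median 1.01, adjusted p = 0.00291, and adjusted p = 0.771 with an estimated correlation), with 1 member called either way. The erythroid list fell (median -1.36, adjusted p = 9.5e-05), with 3 members lower over all genes and 7 adjusted over the list alone. The collagen and basement membrane list fell (median -0.36, adjusted p = 0.00178), with 1 member higher and 2 lower over all genes, and 1 higher and 3 lower adjusted over the list alone. The oocyte list (median -0.31, adjusted p = 0.00573) and the proteoglycan and matrix glycoprotein list (median -0.24, adjusted p = 0.0466) fell, with 0 and 1 members lower over all genes, and 2 and 1 adjusted over the list alone. For the erythroid, collagen, oocyte and proteoglycan lists the adjusted p = 0.357 with an estimated correlation. The oocyte call ended without wild-type replicate 2 of 61 dpf (adjusted p = 0.0951). The proteoglycan call ended without wild-type replicates 1 (0.0658) and 3 (0.0854) of 47 dpf and replicates 1 (0.168) and 2 (0.114) of 61 dpf, and its median was -0.40 without replicate 3 of 61 dpf. The median was 0.63 for macrophage and neutrophil genes without replicate 1 of 61 dpf and -0.67 for erythroid genes without replicate 3 of 47 dpf. For the collagen and basement membrane list it was -0.22 without replicate 1 of 47 dpf.

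The number of wild-type age calls was 34, 16 and 93 without replicates 1, 2 and 3 of 47 dpf, and 848 and 51 without replicates 1 and 3 of 61 dpf. DESeq2 called 1670 genes, a fit of the compared libraries alone 26 and a test against a fold of 2 called 4. Of the 10 named genes, 0 were called without replicate 1 or 2 of 47 dpf or replicate 3 of 61 dpf, 1 without replicate 3 of 47 dpf, and 8 without replicate 1 or 2 of 61 dpf.

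In mutant ovary erythroid genes were lower at 61 than at 47 dpf, as a group (median -0.95, camera adjusted p = 1.88e-12, and adjusted p = 0.202 with an estimated correlation), with 0 members called over all genes and 7 lower adjusted over the list alone. The collagen and basement membrane list was lower (median -0.17, adjusted p = 0.0129, and adjusted p = 0.71 with an estimated correlation) and the MMP and TIMP list higher (median 0.26, adjusted p = 0.00765, and adjusted p = 0.552 with an estimated correlation), with no member called either way. Markers of liver (median -1.19, adjusted p = 9.65e-06), exocrine pancreas (-1.78, adjusted p = 0.00645) and skeletal muscle (-2.62, adjusted p = 0.000136) were lower as groups, each with an adjusted p = 0.71 with an estimated correlation. No member of these was called over all genes, and adjusted over the list alone 1 liver gene was lower, no pancreas gene passed, and 2 muscle genes were higher and 10 lower. These calls ended without single libraries. The liver call ended without replicate 1 of 47 dpf (median 0.18, adjusted p = 0.74), and the muscle call without replicate 2 of 47 dpf (median -0.47, adjusted p = 0.423). Without replicate 1 of 61 dpf the liver median was -1.92, and the pancreas median was -0.78 and -3.08 without replicate 3 of 47 dpf and replicate 3 of 61 dpf. The pancreas call ended without replicates 1 (0.294) and 3 (0.537) of 47 dpf, and without replicate 2 of 61 dpf, where the median was -1.27 with 1 of 17 members positive and camera's direction against the other genes was up (0.974). The collagen call ended without replicate 2 of 47 dpf (0.264) and replicates 1 (0.11) and 3 (0.0604) of 61 dpf, and the MMP and TIMP call without replicate 3 of 47 dpf (0.182) and replicate 2 of 61 dpf (0.0713), with a median of 0.16 without replicate 3 of 47 dpf or replicate 1 of 61 dpf.

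edgeR called 0 genes between the ages in mutant (smallest adjusted p = 0.598), 820 had an unadjusted p under 0.05, DESeq2 called 22 and limma voom 0. Without replicates 2 and 3 of 47 dpf edgeR called 1 and 7 genes. Of the 325 wild-type age calls, 250 had the same sign in mutant, against 59.9% of all tested genes with the same age sign in both genotypes, with a median log2 change along the wild-type direction of 0.23 in mutant and 1.56 in wild type, on which these genes were chosen.

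No gene passed edgeR's test of a difference in the mutant effect between 61 and 47 dpf (smallest adjusted p = 0.0871). The same contrast is the difference between the age changes of mutant and wild type. The genes with the smallest p were smyhc3, a slow myosin gene that was at 0 in every wild-type library of 61 dpf and at 0.848 to 1.15 CPM on average in the other groups, cmah (-2.24, adjusted p = 0.115), ptgis, a prostacyclin synthase gene (3.31, adjusted p = 0.135), mmp16b (2.22, adjusted p = 0.163), abhd6a (2.11, adjusted p = 0.185) and olfcq14 (1.37, adjusted p = 0.21). An unadjusted p under 0.05 was found for 1811 genes, DESeq2 called 108 genes, and limma voom called 0. edgeR called 3 genes without wild-type replicate 1 and 1 without mutant replicate 2 of 47 dpf, 2 without mutant replicate 2, and 1 each without wild-type replicates 1 and 3 of 61 dpf. By camera with the preset correlation the mutant effect on matrix proteoglycan and MMP and TIMP genes was higher at 61 dpf (adjusted p = 0.0159 and 0.00298) and that on vitellogenin genes lower (adjusted p = 1.66e-06), with an adjusted p = 0.296 for each with an estimated correlation. The proteoglycan call ended without mutant replicate 1 (adjusted p = 0.0772) or wild-type replicate 3 (0.0504) of 47 dpf, or mutant replicate 2 (0.065) or wild-type replicate 1 (0.0661) of 61 dpf. No member of these lists was called over all genes, and 1 MMP and TIMP gene was higher, 6 vitellogenin genes were lower and no proteoglycan gene passed adjusted over the list alone.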

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

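The tests of liver RNA for vitellogenin, the alternatives for the lists of the difference of the mutant effect and their medians without a library, and the look at the split with 17 genes were chosen after the results were seen. A test of the difference itself marked the mutant effect on 6 gene lists as different between 61 and 47 dpf, by camera with the preset correlation. For the proteoglycan and matrix glycoprotein list (adjusted p = 0.0159) and the MMP and TIMP list (adjusted p = 0.00298) the effect was higher at 61 dpf, with median differences of 0.43 and 0.54 on the log2 scale and 28 of 38 and 21 of 29 members positive. For vitellogenin (adjusted p = 1.66e-06, median difference -5.07, 0 of 6 positive), exocrine pancreas (0.00172, -2.32, 0 of 17 positive), liver (0.0159, -1.31, 3 of 23 positive) and macrophage and neutrophil (0.0459, -0.61, 7 of 28 positive) it was lower. With an estimated correlation the adjusted p was 0.296 for the matrix lists and vitellogenin, 0.878 for exocrine pancreas and 0.879 for the other lists.

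Some of these differences rested on single libraries. The macrophage and neutrophil difference was lost without mutant replicate 1 of 47 dpf (adjusted p = 0.98), mutant replicates 1 (0.0627), 2 (0.065) and 3 (0.0715) of 61 dpf, wild-type replicates 2 (0.0906) and 3 (0.134) of 47 dpf, and wild-type replicates 1 (0.0661) and 3 (0.174) of 61 dpf. The liver difference was lost without mutant replicate 1 of 47 dpf (0.831), mutant replicates 2 (0.099) and 3 (0.116) of 61 dpf, wild-type replicates 2 (0.0906) and 3 (0.0743) of 47 dpf, and wild-type replicates 1 (0.0661) and 3 (0.0812) of 61 dpf. The proteoglycan difference was lost without mutant replicate 1 (0.0772) or wild-type replicate 3 (0.0504) of 47 dpf, or mutant replicate 2 (0.065) or wild-type replicate 1 (0.0661) of 61 dpf, and the pancreas difference without mutant replicate 2 of 61 dpf (0.0914) or wild-type replicate 2 of 47 dpf (0.0906). Without mutant replicate 1 of 47 dpf the median difference was 0.32 for liver and -0.086 for macrophage and neutrophil, and without mutant replicate 1 of 61 dpf it was -2.17 for liver. For pancreas it was -1.44, -3.70 and -4.04 without mutant replicate 3 of 47 dpf, mutant replicate 3 of 61 dpf and wild-type replicate 1 of 47 dpf. The line of the table without a gene name, which no comparison used, held counts of up to 0.000113% of a library.

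Age changes called in wild-type ovary were not called in mutant ovary. This is a difference in calls and does not show for any single gene that the age change differed between genotypes. The direct test of that is the same contrast as the difference of the mutant effect between ages. For it edgeR called 0 genes (smallest adjusted p = 0.0871). Whether the choice of genes on wild-type libraries was the cause cannot be decided here. In a model of age alone 117 genes had an unadjusted p under 0.001. Their median age change was 1.5 in wild type and 1.09 in mutant, a median difference of -0.39. A one-sided share of 0.025 of the splits of the genotype labels (10 of 400) gave a difference as far below 0. But wild-type libraries also entered that choice of genes, and the splits take the groups as equally spread. At 61 dpf the median SD of log2 CPM was 0.443 in wild type and 0.229 in mutant. A single wild-type library of 61 dpf is argued against as the whole cause only. Age calls numbered 848, 458 and 51 without replicates 1, 2 and 3, and the difference stayed at -0.25, -0.39 and -0.30. The test asked only that the calls stay above 0 and the difference below 0. The calls did lean on replicate 3, without which 0 of the 10 named genes of the wild-type age change were called. Whether the mutant ovary at 61 dpf stayed near the profile of wild type at 47 dpf cannot be told apart from other causes that set the wild-type libraries of 61 dpf apart: 17 genes (10 higher, 7 lower) were called between these groups, but with 0 calls for the mutant age change and 19 for mutant at 47 dpf few were left to find. Of the 325 wild-type age calls 250 had the same sign in mutant, against 59.9% of all tested genes with the same age sign in both genotypes, and a difference in stage between the sampled fish was not tested.

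Vitellogenin transcripts, made mainly by liver, rose from 47 to 61 dpf in wild-type ovary by a median of 6.25 on the log2 scale. More liver RNA carried over at 61 dpf is argued against: the median change of 23 liver genes was -0.06, with an upper 95% bootstrap bound of 0.25, and the test needed it to stay below 3.04, halfway to the lowest called vitellogenin change of 6.09. The most abundant liver genes stayed near their level, with fetub at 11.6 ± 4.82 and 12.5 ± 3.3 CPM, apoc2 at 7.22 ± 1.96 and 5.94 ± 1.88 CPM, and rbp4 at 6.36 ± 1.17 and 4.81 ± 1.68 CPM at 47 and 61 dpf (SD, n = 3 each). The bootstrap drew genes and not libraries, and liver genes varied together (estimated correlation 0.582), so its bound leaves out the spread between libraries. The summed level of the liver list in wild-type replicates 1, 2 and 3 was 76.2, 41.3 and 44.1 CPM at 47 dpf. At 61 dpf it was 60.1, 36.4 and 55.1 CPM. Of the 23 liver genes, 10 had a mean of at least 1 CPM in wild-type ovary at 47 dpf and 0 are in another list. A constant trace of liver RNA in which vitellogenin itself had risen cannot be told apart from expression in the ovary, since the vitellogenin share of liver RNA was not measured here.

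For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real number of calls and the highest of the other splits were 19 and 1 for mutant at 47 dpf, 390 and 2 for mutant at 61 dpf, 325 and 2 for the wild-type age change, and 0 and 1 for the mutant age change (820 genes at an unadjusted p under 0.05, DESeq2 22 and limma voom 0). For the difference of the mutant effect 100 of 100 splits drawn gave as many genes as the real 0, but with a real count of 0 every split gives as many, so the splits decide nothing here (1811 genes at an unadjusted p under 0.05, DESeq2 108 and limma voom 0). The highest other split gave 17 genes; it kept the 3 wild-type libraries of 61 dpf in place and mixed the genotypes at 47 dpf.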

How the results depend on the processing

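The alternatives for the lists and genes of the age comparisons and of the difference of the mutant effect, for the overlap of the ages and for the chromosome of adamts9, were chosen after seeing the data. The named genes that were called kept their sign under the 14 alternatives run for single genes, which leave out the minimum fold of 2, and 3 of 11 at 47 dpf, 6 of 34 at 61 dpf and 0 of 10 for the wild-type age change stayed called under all 14, with adjusted p-values of up to 0.252, 0.162 and 0.161. Called under all 14 were ogfrl2, rpusd4 and tmf1 at both ages, and uba3, cdh4 and cmah at 61 dpf. All of these but cmah were placed on the chromosome of adamts9, near it in gene order. At 61 dpf gsdf was called under 6 and fshr under 8 of the 14. Leaving out a library leaves fewer samples, which can end calls by its construction. For the other changes given here the cause was not tested. Depth and the spread between libraries limit small changes: on simulated counts 11.9% of the genes changed by a fold of 2 were recovered at each age, and a count of 0 allows 0.0774 to 0.182 CPM. In wild type at 47 dpf vtg4 was at 0.0774 CPM and vtg7 at 0.103 CPM on average, under the 0.108 to 0.126 CPM that a count of 0 allows in those libraries, so the size of their rise with age is uncertain.

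With DESeq2's Wald test the calls were 173 at 47 dpf, 2387 at 61 dpf, 108 for the difference of the mutant effect, 1670 for the wild-type age change and 22 for the mutant age change. It placed 39 and 102 calls of 47 and 61 dpf on the chromosome of adamts9, found 53 genes higher and 18 lower at both ages, and gave the same sign for 152 of its 47 dpf calls and 1864 of its 61 dpf calls at the other age. Against a minimum fold of 2 the calls were 10 at 47 dpf, 9 at 61 dpf and 4 for the wild-type age change, with 5 and 5 on the chromosome of adamts9, 3 higher and 4 lower at both ages, and the same sign for 9 and 8 of the calls. In fits of the compared libraries alone 20 genes were called at 61 dpf, 7 of them on that chromosome and 16 with the same sign at 47 dpf. In these fits 3 genes were higher and 4 lower at both ages, and 26 were called for the wild-type age change. Such fits estimate the spread from fewer samples, while the main fit shares it over 4 groups of unequal spread. The median SD of log2 CPM was 0.443 in wild type at 61 dpf and 0.229 to 0.302 in the other groups. Their parts in the lower counts were not tested. With upper-quartile factors 989 genes were called at 61 dpf, 51 on that chromosome and 797 with the same sign at 47 dpf. Leaving out the genes placed on that chromosome, 9 calls were left at 47 dpf, of which 5 have no place. All other alternatives but the block and the libraries left out moved no count by over 1.5 times.

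The same replicate numbers were not taken to pair the samples, since in no comparison were all 3 correlations over 0.1. Libraries of the same number correlated, in their deviations from the group means, at 0.035, 0.068 and 0.254 at 47 dpf and at 0.023, 0.008 and -0.016 at 61 dpf, and not every library correlated best with its own number. Between the ages the same numbers correlated at 0.094, 0.073 and 0.161 in mutant, where each library correlated best with its own number, and at -0.198, 0.016 and 0.021 in wild type. With a replicate block 87 genes were called at 61 dpf, 13 on the chromosome of adamts9 and 68 with the same sign at 47 dpf, and 115 for the wild-type age change. The block changed the direction of the spermatid and axoneme list at 61 dpf (adjusted p = 0.966), and the wild-type age change of cyp17a1 was 0 with the sign turned. It ended no list call, and 5 of 11 named genes at 47 dpf, 16 of 34 at 61 dpf and 3 of 10 for the wild-type age change were called with it.

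With a library left out the calls ranged from 27 to 1639 at 61 dpf, from 16 to 848 for the wild-type age change, from 0 to 7 for the mutant age change and from 0 to 3 for the difference of the mutant effect. The calls on the chromosome of adamts9 ranged from 6 to 10 at 47 dpf and from 10 to 67 at 61 dpf, genes higher at both ages from 3 to 9, genes lower at both from 5 to 10, and calls with the same sign at the other age from 11 to 23 for 47 dpf and from 20 to 1297 for 61 dpf.

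None of the genes whose sign turned was called. With upper-quartile factors bmp15 was at 0.03 at 47 dpf, gdf9 at 0.04 at 61 dpf and sox9a at -0.08 for the wild-type age change. mmp16b at 47 dpf was at -0.02 with DESeq2 and with median-of-ratios factors, at -0.01 with no filter and at 0 in the compared libraries alone, and the wild-type age change of cyp17a1 was 0 with DESeq2 and with median-of-ratios factors. With a library left out, log2 fold changes in mutant at 47 dpf ranged for amh from -0.23 to 0.04, bmp15 from -0.17 to 0.18, ckma from -0.26 to 3.49, cmah from -0.05 to 0.31, cyp11c1 from -0.31 to 0.56, cyp17a1 from -0.36 to 0.01, figla from -0.04 to 0.24, fshr from -0.01 to 0.25, gsdf from -0.05 to 0.51, mmp16b from -0.13 to 0.11, mylz3 from -0.17 to 4.2, tpma from -0.24 to 3.6 and zp3b from -0.04 to 0.15. At 61 dpf adamts9 ranged from -0.11 to 0.18, amh from -0.47 to 0.15, cyp17a1 from -0.10 to 0.25, dmrt1 from -1.20 to 0.54 and pgr from -0.10 to 0.27. For the wild-type age change amh ranged from -0.10 to 0.52, cyp17a1 from -0.21 to 0.15 and sox9a from -0.16 to 0.54.

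Every list call was lost with a correlation estimated from the data. In mutant at 47 dpf the adjusted p with an estimated correlation was 0.485 for ADAMTS family, 0.156 for MMP and TIMP, 0.151 for collagen and basement membrane, 0.151 for endothelial and mural, 0.623 for exocrine pancreas, 0.151 for granulosa cell, 0.18 for immediate early, 0.275 for liver, 0.156 for macrophage and neutrophil, 0.156 for proteoglycan, 0.621 for skeletal muscle and 0.151 for testis somatic cell. At 61 dpf it was 0.746 for ADAMTS family, 0.0558 for MMP and TIMP, 0.162 for collagen, 0.37 for lymphocyte, 0.839 for macrophage and neutrophil, 0.0558 for proteoglycan, 0.252 for testis somatic cell and 0.252 for vitellogenin. For the wild-type age change it was 0.771 for macrophage and neutrophil and 0.357 for collagen, erythroid, oocyte, proteoglycan and vitellogenin. For the mutant age change it was 0.552 for MMP and TIMP, 0.202 for erythroid and 0.71 for collagen, exocrine pancreas, liver and skeletal muscle. For the difference of the mutant effect it was 0.296 for MMP and TIMP, proteoglycan and vitellogenin, 0.878 for exocrine pancreas and 0.879 for liver and for macrophage and neutrophil.

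The rotation test fry, which does not compare a list with other genes, called some lists that camera called and not others. At 61 dpf its adjusted p was 0.000363 for MMP and TIMP, 0.000489 for proteoglycan and 0.00115 for collagen. It was 0.00454 for testis somatic cell, 0.0198 for vitellogenin and 0.0237 for lymphocyte. At 47 dpf it was 0.0277 for collagen and 0.0457 for both MMP and TIMP and proteoglycan. The lists that follow were called by camera and not by fry. Its adjusted p at 47 dpf was 0.24 for ADAMTS family, 0.604 for exocrine pancreas, 0.0659 for immediate early, 0.182 for liver, 0.0659 for macrophage and neutrophil and 0.489 for skeletal muscle. At 61 dpf it was 0.0933 for ADAMTS family and 0.252 for macrophage and neutrophil, and for the wild-type age change 0.324 for macrophage and neutrophil. For the mutant age change it was 0.49 for MMP and TIMP, 0.683 for collagen, 0.13 for erythroid and 0.756 for exocrine pancreas, liver and skeletal muscle. For the difference of the mutant effect it was 0.138 for MMP and TIMP, 0.769 for exocrine pancreas, 0.849 for liver, 0.849 for macrophage and neutrophil, 0.163 for proteoglycan and 0.138 for vitellogenin. Its direction was the opposite of camera's, with no call by either, at 0.975 for erythroid, germ cell and piRNA, spermatid and axoneme, and steroidogenesis at 47 dpf, and at 0.892 for erythroid, 0.927 for granulosa cell and 0.82 for spermatid and axoneme at 61 dpf.

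With no filter on low counts, camera's adjusted p was 0.054 for ADAMTS family at 61 dpf and 0.0609 for macrophage and neutrophil in the difference of the mutant effect, both no longer called, and 0.0277 for lymphocyte at 47 dpf, then called. Its direction turned for erythroid at 47 dpf (0.932), spermatid and axoneme at 61 dpf (0.879) and steroidogenesis at 61 dpf (0.879). With the compared libraries alone MMP and TIMP and skeletal muscle were lost for the mutant age change (0.0661 each) and skeletal muscle was called at 61 dpf (0.00858), and directions turned for erythroid at 47 dpf (0.837), erythroid at 61 dpf (0.862) and steroidogenesis at 61 dpf (0.886). With median-of-ratios factors directions turned for erythroid at 47 dpf (0.95), erythroid at 61 dpf (0.971) and spermatid and axoneme at 61 dpf (0.971). With upper-quartile factors lymphocyte and macrophage and neutrophil were lost at 61 dpf (0.0644 each), proteoglycan for the wild-type age change (0.0532), exocrine pancreas was called at 61 dpf (0.0256) and steroid and progestin receptor turned at 47 dpf (0.937). Without the 50 most abundant genes oocyte (0.0729) and proteoglycan (0.0548) were lost for the wild-type age change.

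With a library left out, camera's adjusted p at 47 dpf ranged for ADAMTS family from 0.0159 to 0.0926, cell cycle 0.348 to 0.979, erythroid 0.0624 to 0.725, exocrine pancreas 1.93e-11 to 0.624, germ cell and piRNA 0.431 to 0.979, granulosa cell 0.0037 to 0.0535, immediate early 0.000378 to 0.123, lymphocyte 0.0177 to 0.338, meiosis 0.029 to 0.786, skeletal muscle 3.4e-08 to 0.926, spermatid and axoneme 0.615 to 0.956, steroid and progestin receptor 0.466 to 0.961 and steroidogenesis 0.543 to 0.979. At 61 dpf it ranged for ADAMTS family from 0.00448 to 0.31, cell cycle 0.31 to 0.923, erythroid 0.639 to 0.969, exocrine pancreas 0.00865 to 0.799, granulosa cell 0.692 to 0.983, immediate early 0.0446 to 0.603, liver 0.0741 to 0.854, lymphocyte 0.0127 to 0.134, macrophage and neutrophil 0.00919 to 0.384, meiosis 0.458 to 0.923, oocyte 0.00718 to 0.749, spermatid and axoneme 0.321 to 0.969, steroidogenesis 0.722 to 0.954 and testis somatic cell 0.0031 to 0.0598. For the wild-type age change the ranges were 0.000169 to 0.0951 for oocyte and 0.00556 to 0.168 for proteoglycan. For the mutant age change they were 0.000428 to 0.182 for MMP and TIMP, 0.0022 to 0.264 for collagen, 1.75e-14 to 0.974 for exocrine pancreas, 7.55e-15 to 0.74 for liver and 1.07e-09 to 0.423 for skeletal muscle. For the difference of the mutant effect they were 7.96e-09 to 0.0914 for exocrine pancreas, 1.49e-05 to 0.831 for liver, 0.000201 to 0.98 for macrophage and neutrophil and 0.0022 to 0.0772 for proteoglycan. Of the lists that were not called, 13 of 266 alternatives made a call for the wild-type age change, 4 of 266 for the mutant age change and 7 of 361 for the difference of the mutant effect, and none did so with the opposite sign.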

Other observations

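The tests of gene position near adamts9 were chosen after the results were seen.

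The placed genes called in mutant against wild type lay on the chromosome of adamts9 far more often than other genes. An uneven spread by chance is argued against, with a Fisher's exact p of 8.34e-05 for the weaker of the ages after multiplying by the 25 chromosomes, and the wild-type age calls had a share of 4.53% there (Fisher's exact p = 0.374). Changes that follow the loss of adamts9 wherever a gene lies are argued against for the calls at 47 dpf as a whole. The lower 95% bound of the share of placed calls on that chromosome was 41.9%, and 3.48% of tested genes lie there. This bound and Fisher's exact test take genes as independent, which neighbouring genes need not be. Alleles of the flanking chromosome carried along with the mutation may account for the calls nearest to adamts9, in line with their shorter distance in gene order (permutation p = 1e-05, the smallest possible). Local effects of the mutation itself on neighbouring genes were not tested apart from this, and of the 390 calls at 61 dpf 278 were placed elsewhere and 84 were not placed.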
